A study of Homo sapiens with 24 samples.

How the data were processed

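Mature miRNAs were measured in 4 human cancer cell lines, H23 and H460 from lung and OVCAR3 and A2780 from ovary. Each line was studied in 3 states: the cisplatin-sensitive parental cells (S), a cisplatin-resistant variant obtained by exposing those cells to rising cisplatin doses (R), and the resistant variant after the demethylating agent 5-aza-2'-deoxycytidine and the histone deacetylase inhibitor trichostatin A (RT). Each of the 12 groups was hybridised on 2 arrays, giving 24 arrays. Group and replicate number were taken from the sample labels. The labels describe hybridisation in duplicate and do not say that the duplicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

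Per the file headers, the authors scanned single-colour (Cy3) Agilent human miRNA arrays and extracted them with Feature Extraction 10.1.1.1, and the submitters' processing notes name Agilent Feature Extraction 10. The deposited scanner files hold spot intensities, of which the processed signal, corrected for background by that program, was used. Per the file headers, the authors' files also carry a detection flag (well above background), outlier flags and a total signal per miRNA. The authors' deposited series matrix holds 1 log2 value per miRNA and array. Its scale was identified as log2 by setting each column against the scanner values, its direction is that of the signal, and its normalisation and centring are not given in the sources used here. Column medians of that matrix ran from 1.51 to 2.00. Of its 24 columns, 12 tracked their own array best and 12, all of H460 and A2780, tracked the other replicate of the same group, so group means were little affected.

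Each array held 12784 non-control spots for 2421 probes of 795 miRNA names, 719 of them human (2125 probes) and 76 viral. Names are those of the array design, which can be old, and an asterisk marks the minor arm of a hairpin. The array design was annotated on an older genome build than the reference supplied, so no coordinates are given. Control spots and spots with an outlier flag were left out, the remaining spots of a probe were averaged, and each array was divided by its 75th percentile over the 82 human probes detected on all 24 arrays. Values below 2.66% of that reference, the median over arrays of the lowest detected scaled signal, were set to that floor. Log2 was then taken and averaged over the probes of a miRNA. A probe counted as detected on an array when more than 0.5 of its spots were well above background. The 237 human miRNAs with a probe detected on both arrays of at least 1 group were tested, and 42.9% of their values lay at the floor. A fold change can therefore understate the change of a dim miRNA. It can also overstate it where the lowest detected signal of an array lay above the floor of 0.0266 of the reference. That signal was 0.0337 and 0.0437 on the H23 R arrays and 0.0983 on H460 R replicate 2.

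The reference percentile ranged from 339 to 1244 intensity units (median 740), the human miRNAs detected per array from 86 to 175, and no non-control spot was saturated (0 spots). The weakest array was H460 R replicate 2, at 339 units and 146 detected human probes. Duplicate arrays correlated across miRNAs with r from 0.978 to 0.998, and miRNAs are not independent replicates. With 2 arrays per group, the number of arrays limits the precision. Slide and scan batch coincided on every array, leaving 3 batches of 8 arrays. All groups of H23 and OVCAR3 had 1 array on slide 1 and 1 on slide 2. In these lines the slide as a block cannot alter a fitted change, only its p. Calls were also chosen on these same arrays, so their keeping a direction within both slides adds little further evidence. For H460 and A2780, S and R shared only slide 3, with 1 array each, and RT lay on slide 3 alone.

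Changes within a line (R against S, RT against R) were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with files read by version 1.17.8 of the data.table package. A single fit of 12 group means to all 24 arrays had 12 residual degrees of freedom. A group wholly at the floor adds a spread of 0 to that fit. Standard errors and p-values are therefore too small for miRNAs at the floor in many groups. With a minimum spread, the median spread of miRNAs detected on all arrays, 443 named values kept their side of the threshold, 2 rose above it and 0 dropped below. limma estimates its prior spread anew in that fit, and calls rose in some contrasts, from 20 to 22 for R against S in A2780. It therefore cannot show that the calls withstand a larger spread. p-values were adjusted by the Benjamini-Hochberg method over the 237 miRNAs, and a miRNA was called at an adjusted p under 0.05 with at least a 2-fold change. All adjusted p-values and standard errors of single miRNAs come from limma. Across lines, the duplicates were averaged, the line was the replicate and entered as a block (6 residual degrees of freedom), and calls needed an adjusted p under 0.05. limma's moderated F test asked whether the 4 lines changed alike, and the 2 lung lines were set against the 2 ovarian lines on their line differences.

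Where no probe of a miRNA was well above background on any array of 1 group, the change is given as at least N-fold. This bound sets the brighter group's mean, over the probes detected on both its arrays, against the mean over the dimmer group's arrays of the higher of each array's lowest detected signal and the probe's own signal. The adjusted p beside such a bound is that of the fitted change. Calls also rest on the fitted change, so a called miRNA can have a bound under 2-fold. Values at the floor have no order, so bounds are not ranked.

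The lists of miRNAs, the rule for naming miRNAs and the alternatives below, except those stated as added, were set before the data were examined. There were 17 lists: study candidates, miRNAs reported as silenced by promoter methylation, the C19MC cluster, the miR-371 to miR-373 and miR-302 with miR-367 clusters, the Xq27 miR-506 to miR-514 and miR-888 clusters, the 14q32 imprinted cluster, the miR-200 family, the let-7 family, the miR-17-92 cluster with its paralogs, p53-induced miRNAs, the HOX clusters, miRNAs reported in cisplatin response, and markers of blood and endothelium, muscle, stroma, liver and neurons. Of these, 14 had at least 3 tested members and were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 112 tests within lines and, separately, over 42 across lines. Within lines, 12 tests passed with the preset correlation and 4 with an estimated one; across lines, 12 and 0. The study candidates (miR-7, miR-132, miR-335 and miR-148a) were recalled from the study's publication and so were chosen on these samples. miR-9, miR-34b, miR-34c, miR-124, miR-127, miR-148a, miR-214 and miR-512 stand in more than 1 list, so lists that share them are not independent.

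The miRNAs named in the text were chosen by rule: in each line and contrast the 5 largest called rises and the 5 largest called falls with no overlap between the arrays of the groups, up to 3 of the smallest p-values in each direction where an across-lines contrast called none, up to 5 miRNAs per line that fell in R and rose in RT, up to 4 members of each list by mean absolute change, and the study candidates. Other called miRNAs named in counts or lists were chosen after their values were seen.

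The tests were run on simulated data with known changes, though the fits to the real values had been run once before that. In 20 draws on the arrays of H23 R against S, with 60 of 237 miRNAs changed, 98.8% of changes of 1.5 and 99.8% of changes of 2 on the log2 scale were called in the right direction, and 0.0847% of unchanged miRNAs were called. For R against S across lines the shares were 92.8%, 94.2% and 1.21%. The floor was not applied to the simulated values, and miRNAs at the floor were given little or no spread. Falls of miRNAs already at the floor thus counted as seen, so these shares overstate what the tests can find in the real values. The reversal counts were set beside 100 draws of unchanged groups and, as chosen after the data were seen, beside counts and covariances with 1 R array for each change.

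The alternatives tried were quantile normalisation, the total signal per miRNA, the brightest probe per miRNA, the series matrix, no detection filter, detection on all 24 arrays, the slide or the replicate number as a block, only the arrays of a line, no minimum fold, an estimated correlation and leaving out each array or line. Normexp background correction (offset 50) of the median signal, a minimum spread, and leaving out the weakest array were added after seeing the data.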

Results

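The arrays compared parental cisplatin-sensitive cells (S), cisplatin-resistant cells (R) and resistant cells treated with 5-aza-2'-deoxycytidine and trichostatin A (RT) in 4 human cancer cell lines. H23 and H460 came from lung and OVCAR3 and A2780 from ovary, with 2 arrays in each of the 12 groups. Between 86 and 175 human miRNAs were detected per array. In H23, 145 miRNAs were detected on both S arrays, 87 on both R arrays and 132 on both RT arrays. The corresponding counts were 132, 83 and 117 in H460, 125, 139 and 169 in OVCAR3, and 100, 119 and 152 in A2780. Changes are given on the log2 scale with their standard error and the adjusted p of limma, each from 2 arrays per group, and all levels are percentages of the array reference signal.

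miR-7, known as a repressor of EGFR signalling, was lower in resistant than in parental cells of H23 and A2780 and higher after the drugs in both lines. In H23 its level was 26.7% in S, below detection in R and 6.33% in RT, a fall of at least 6.95-fold (adjusted p = 6.15e-09) and a rise of at least 3.08-fold (adjusted p = 8.03e-05). In A2780 it was 29.2% in S, 3.59% in R and 110% in RT, a change of -3.03 ± 0.18 in resistance (adjusted p = 1.64e-08) and of 4.93 ± 0.18 with the drugs (adjusted p = 1.70e-10). In H460 (10.8%, 6.69% and 10.8%) and OVCAR3 (6.40%, 10.06% and 19.03%) each change was under 2-fold. The H460 changes were -0.70 ± 0.18 (adjusted p = 0.0377) and 0.69 ± 0.18 (adjusted p = 0.0205), and the OVCAR3 changes 0.65 ± 0.18 (adjusted p = 0.0211) and 0.92 ± 0.18 (adjusted p = 0.00107). The 4 lines differed in both contrasts beyond the spread between duplicate arrays (moderated F test of limma, adjusted p = 5.23e-08 and 5.03e-09). Within slides 1 and 2 the H23 fall was at least 8.30-fold and at least 5.83-fold and the rise at least 4.15-fold and at least 2.28-fold, and within slide 3 the A2780 changes were -3.06 and 5.02. With the slide as a block the A2780 changes were -2.94 and 4.92, and both H23 changes were called. The H23 rise was no longer called without RT replicate 1 (0.95, fitted against R at the floor), with quantile normalisation, with normexp correction or with only the arrays of that line.

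**Figure D1:**
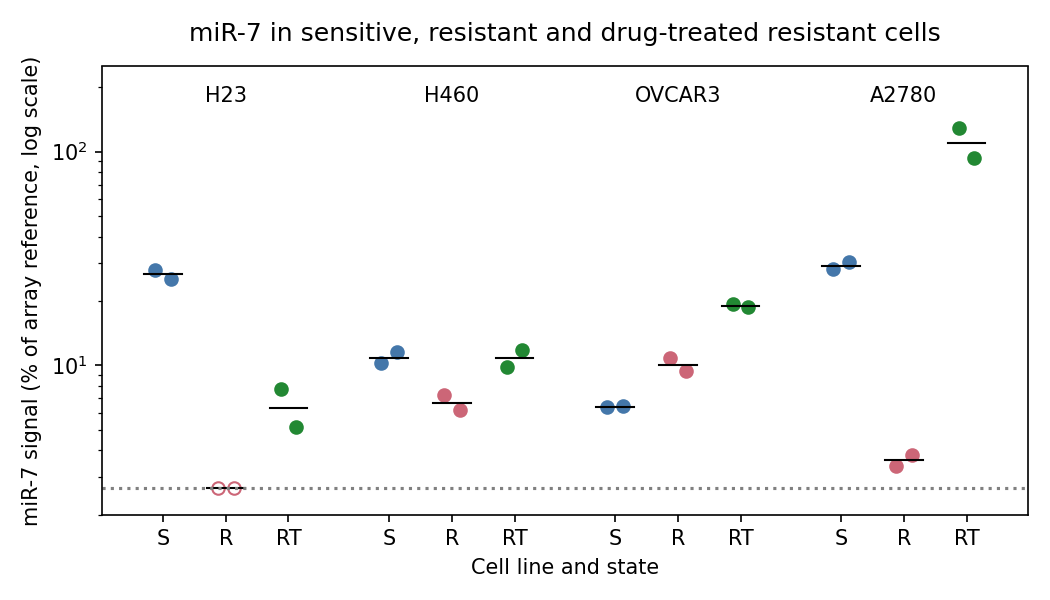
miR-7 signal on each array as a percentage of the array reference (log axis) in the 12 groups, with filled points where a miR-7 probe was well above background, open points where none was, black lines at the group mean of the log2 values and a dotted line at the floor. The mean was 26.7% in H23 S and at the floor in H23 R, and rose from 3.59% in A2780 R to 110% in A2780 RT.

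Of the other study candidates, miR-132 was called in H23 and A2780, miR-335 in A2780 and miR-148a in no line. miR-132 was at 8.88% in H23 S, 3.69% in R and 20.7% in RT, falling with resistance (-1.26 ± 0.10, adjusted p = 2.28e-07) and rising with the drugs (2.49 ± 0.10, adjusted p = 4.83e-11). In A2780 R it was not well above background on either array and rose at least 6.21-fold in RT (adjusted p = 1.48e-09). miR-335 fell from 51.4% to 12.8% in A2780 R (-2.01 ± 0.09, adjusted p = 9.87e-10), as did its minor arm miR-335* (-2.58 ± 0.16, adjusted p = 1.64e-08), and stood at 13.8% after the drugs. miR-148a was not well above background in H23 R (at least 1.103-fold lower) and had values of -0.78 ± 0.22 in H460 R, 0.92 ± 0.22 in OVCAR3 R and -0.67 ± 0.22 in A2780 R. As a list, the candidates were lower in A2780 R (3 of 6 tested members called, 3 adjusted over the list alone, camera adjusted p = 2.48e-04) and higher in A2780 RT (2 of 6, 2 adjusted over the list alone, adjusted p = 0.00102). With an estimated correlation the adjusted p were 0.102 and 0.155, and since the list was chosen on these samples it is not independent evidence of direction. In H23, 2 of 6 fell and 2 rose, also 2 and 2 adjusted over the list alone, with no camera call. The list medians in A2780 were -1.34 and 0.39, -1.15 and 0.34 within slide 3, and the latter was 1.09 with total signals, 0.71 with the brightest probe and 1.57 with the series matrix. The miR-335 call was lost with the series matrix and the H23 miR-132 fall with quantile normalisation and normexp correction.

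In H23, 23 miRNAs fell and 4 rose with resistance. Both R arrays were dim, with reference signals of 499 and 494 against 718 and 871 in S and 99 and 88 human miRNAs detected against 152 and 150, and 12 of the 27 calls had 1 group with no detection. Besides miR-7, miR-582-5p fell at least 4.66-fold (adjusted p = 1.26e-08), miR-324-5p at least 3.94-fold (adjusted p = 2.80e-07) and miR-9*, from a precursor typical of neurons, at least 3.14-fold (adjusted p = 1.89e-05). miR-19a of the growth-promoting miR-17-92 cluster changed by -2.23 ± 0.37 (adjusted p = 3.31e-04), miR-29b by -2.18 ± 0.37 (adjusted p = 4.32e-04) and miR-21, widely raised in tumours, by -1.19 ± 0.25 (adjusted p = 0.00165). miR-455-3p rose at least 7.37-fold (adjusted p = 1.97e-09), miR-221 by 1.59 ± 0.13 (adjusted p = 3.22e-07), let-7b by 1.39 ± 0.21 (adjusted p = 1.66e-04) and miR-181a by 1.05 ± 0.09 (adjusted p = 5.49e-07). In the miR-17-92 list 7 of 14 tested members fell (7 adjusted over the list alone), among them miR-20b (-1.42), miR-18a (at least 1.89-fold) and miR-363 (at least 1.78-fold). Its median was -0.91, and -0.97 and -0.86 within slides 1 and 2 (camera adjusted p = 0.00279, and 0.664 with an estimated correlation). With normexp correction the median was -0.07 and 0 members were called by limma, and with the series matrix -1.77 and 11. Among the miRNAs reported as silenced by methylation, 2 of 12 fell, miR-9 and miR-9*, which are also the 2 of 3 neuron markers that fell (camera adjusted p = 0.0530, 0.597 with an estimated correlation, 0.0315 with the slide as a block and 0.0264 without H460 R replicate 2), the let-7 family had 1 rise, let-7b, and 1 fall, miR-98, among 9, and miR-21 was the 1 called of 13 in the cisplatin response list. These counts were the same when adjusted over the list alone. All 27 kept their direction within slides 1 and 2, where 27 and 22 were at least 2-fold, and 27 were called with the slide as a block. The split of 4 higher and 23 lower became 9 and 16 with quantile normalisation, 22 and 33 with total signals, 12 and 30 with the brightest probe, 3 and 70 with the series matrix and 3 and 3 with normexp correction. miR-181a (0.95) and miR-21 (-0.96) were not called without R replicate 1, nor miR-9 (-0.94) without S replicate 1, while normexp ended the calls of miR-582-5p, miR-324-5p, miR-19a and miR-9*, and the series matrix those of miR-221 and let-7b.

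In H460, no miRNA changed at least 2-fold with resistance by limma (0 called, 50 at an unadjusted p under 0.05), and 12 passed the adjusted threshold with smaller changes. These included miR-95 (-0.94 ± 0.13, adjusted p = 9.53e-04), miR-10a (-0.47 ± 0.10, adjusted p = 0.0129), miR-629* (0.81 ± 0.14, adjusted p = 0.00440) and let-7c (-0.93 ± 0.23, adjusted p = 0.0347). All 9 tested members of the let-7 family, repressors of RAS, had lower values in R, with a median of -0.61, and 0 were called at 2-fold either over all miRNAs or adjusted over the list alone (limma), against 1 with quantile normalisation or the brightest probe. The median was -1.31 with the series matrix and -0.38 with normexp correction. Camera called this list (adjusted p = 3.90e-06, and 0.379 with an estimated correlation), its median was -0.43 within slide 3, and its adjusted p with the slide as a block was 2.54e-07. The HOX cluster list (miR-10 and miR-196 members) had a median of -0.31 (adjusted p = 0.0108, and 0.352 with an estimated correlation), -0.26 within slide 3, -0.88 with the series matrix and 0.16 with normexp correction. Over all 237 miRNAs the median was -0.44 with the series matrix and 0.32 with normexp correction. Over those detected on all arrays it was -0.58 and 0.07. The weakest array of the series was R replicate 2 of this line. Without R replicate 1, 13 miRNAs were called, against 0 without R replicate 2 and 1 without S replicate 1. Quantile normalisation gave 3 calls and the brightest probe 1.

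In OVCAR3, 9 miRNAs rose and 2 fell with resistance. miR-224 rose by 1.76 ± 0.09 (adjusted p = 5.76e-09), miR-29a by 1.56 ± 0.10 (adjusted p = 2.97e-08), miR-29b by 1.499 ± 0.37 (adjusted p = 0.0117) and the epithelial miR-205 by 1.47 ± 0.04 (adjusted p = 8.23e-12). miR-34a, a p53 target, rose by 1.46 ± 0.12 (adjusted p = 1.03e-06) and was the 1 called member of 4 in the p53-induced list. miR-885-5p, the 1 tested marker of liver, rose by 1.54 ± 0.42 (adjusted p = 0.0208). miR-10b of the HOX clusters changed by -1.32 ± 0.05 (adjusted p = 1.21e-10), the 1 called member of 4, and miR-551b by -1.20 ± 0.15 (adjusted p = 3.13e-05). Each of these 3 list counts was 1 adjusted over the list alone. All 11 kept their direction within slides 1 and 2, with 11 and 10 at least 2-fold, and 11 were called with the slide as a block. The split of 9 higher and 2 lower became 19 and 0 with the series matrix, 30 and 1 with total signals and 6 and 0 with normexp correction. The calls of miR-10b and miR-551b ended with the series matrix and with normexp correction, that of miR-29b without R replicate 1 (1.40) or S replicate 2 (1.40), and that of miR-885-5p with normexp correction and without R replicate 1 (1.56), S replicate 2 (1.08) or R replicate 2 (1.52).

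In A2780, 9 miRNAs rose and 11 fell with resistance. Here the S arrays were the dimmer ones, with reference signals of 787 and 546 against 1163 and 1060 in R. They had 127 and 100 human miRNAs detected against 130 and 120, and 2 of the 20 calls had 1 group with no detection. miR-218 rose by 2.65 ± 0.11 (adjusted p = 9.87e-10), miR-204 by 2.02 ± 0.20 (adjusted p = 4.40e-06), and the let-7 members let-7a, let-7f and let-7e by 2.49 ± 0.28 (adjusted p = 1.24e-05), 2.19 ± 0.31 (adjusted p = 1.33e-04) and 1.58 ± 0.33 (adjusted p = 0.00289). Besides miR-7 and both miR-335 arms, miR-630 changed by -1.81 ± 0.15 (adjusted p = 6.91e-07) and miR-1225-5p by -1.41 ± 0.21 (adjusted p = 2.04e-04). miR-10a and miR-10b of the HOX clusters, 2 of 4 tested members, were not well above background in R and fell at least 5.29-fold and at least 5.04-fold (adjusted p = 1.40e-06 and 1.65e-09). The let-7 family had 3 of 9 members called higher (3 adjusted over the list alone, as were 2 for HOX) and a median of 0.40, against 0.35 within slide 3 (camera adjusted p = 0.00245, and 0.686 with an estimated correlation). Its median and calls were 1.33 and 5 with quantile normalisation, 1.53 and 5 with total signals, 0.79 and 4 with the brightest probe, 2.57 and 9 with the series matrix and -0.27 and 1 with normexp correction. Over all 237 miRNAs the median was 0.31 with the series matrix and -0.85 with normexp correction. Over those detected on all arrays it was 0.52 and -0.30. Within slide 3 all 20 kept their direction, 18 at least 2-fold, and 19 were called with the slide as a block. The split of 9 higher and 11 lower became 26 and 11 with the series matrix and 4 and 22 with normexp correction, which ended the calls of miR-204, let-7f and let-7e. miR-10a (-0.96) was not called without S replicate 1, and with only the arrays of the line 12 miRNAs were called and the let-7 members, miR-630 and miR-1225-5p were not.

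With the drugs, 19 miRNAs rose in H23 and 0 fell at least 2-fold by limma. RT arrays had 134 and 163 human miRNAs detected against 99 and 88 on the dim R arrays, and 12 of the 19 calls had 1 group with no detection. Past the adjusted threshold alone there were 70 higher and 2 lower, and 88 miRNAs had an unadjusted p under 0.05. miR-132 (2.49 ± 0.10) was followed by miR-663 (1.74 ± 0.15, adjusted p = 4.53e-07) and miR-494 (1.75 ± 0.46, adjusted p = 0.00884), and miR-129-3p rose at least 3.85-fold (adjusted p = 4.83e-11). The tested members of the 14q32 imprinted cluster, a maternally expressed miRNA cluster, were higher as a group. 5 of its 14 tested members were called (5 adjusted over the list alone), and all 14 had higher values, including miR-127-3p (at least 2.36-fold, adjusted p = 3.40e-14) and miR-409-3p (at least 1.96-fold, adjusted p = 2.64e-11). The median was 0.71, and 0.83 and 0.64 within slides 1 and 2 (camera adjusted p = 7.16e-13, 1.72e-04 with an estimated correlation and 1.24e-11 with the slide as a block). The median and calls were 2.21 and 14 with total signals, 2.12 and 14 with the series matrix, 1.22 and 10 with the brightest probe and 0.46 and 1 with normexp correction. Of the 63 members on the array, 1 was detected on both arrays in S, 1 in R and 13 in RT. Groups of the other lines had at most 2 detected, so most of the 14 tested members passed the detection filter through H23 RT alone. Their shared direction, median and camera result are therefore partly fixed by the filter, while the detection counts out of 63 are not. Among the miRNAs reported as silenced by methylation 3 of 12 rose, miR-129-3p, miR-127-3p and miR-9* (at least 1.98-fold), and miR-9* was the 1 neuron marker of 3. The p53-induced miR-192 (at least 1.61-fold), miR-363 of the miR-17-92 list (at least 1.54-fold), miR-150* of the blood and endothelium list (at least 1.58-fold) and miR-185 and miR-130b of the cisplatin response list also rose, and these counts were the same when adjusted over the list alone. The C19MC list was called lower by camera (adjusted p = 7.23e-04, and 0.713 with an estimated correlation), although its 32 members were all at the floor, against a median of 0.12 over all tested miRNAs. All 19 kept their direction within slides 1 and 2, with 15 and 15 at least 2-fold, and 19 were called with the slide as a block. Total signals gave 55 higher and 0 lower, the series matrix 34 and 0 and the brightest probe 30 and 0, and with only the arrays of the line 12 were called. Quantile normalisation gave 6 higher and 1 lower and normexp correction 2 calls, and with either miR-663, miR-9*, miR-363, miR-192, miR-185 and miR-150* were no longer called, nor with normexp miR-129-3p, miR-127-3p and miR-409-3p. miR-494 was lost without R replicate 1 (1.53) or RT replicate 2 (1.53), miR-185 (0.94) without RT replicate 1 and miR-150* (0.99) without RT replicate 2.

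In H460, 7 miRNAs rose and 5 fell with the drugs. miR-630 rose by 3.12 ± 0.15 (adjusted p = 2.33e-09), and both arms of the miR-9 and miR-140 hairpins rose, miR-9* by 1.74 ± 0.26 (adjusted p = 3.43e-04), miR-9 by 1.097 ± 0.15 (adjusted p = 1.99e-04), miR-140-3p by 1.43 ± 0.10 (adjusted p = 1.05e-07) and miR-140-5p by 1.36 ± 0.20 (adjusted p = 2.66e-04). miR-21 and miR-21* rose by 1.08 ± 0.25 (adjusted p = 0.0106) and 1.13 ± 0.30 (adjusted p = 0.0228). miR-629* fell at least 2.27-fold (adjusted p = 5.58e-06), miR-371-5p, of a cluster typical of embryonic stem cells, changed by -1.27 ± 0.12 (adjusted p = 5.58e-06) and miR-134 of the 14q32 cluster, detected on 1 R array and 0 RT arrays, by -1.26 ± 0.05 (adjusted p = 6.73e-10). miR-150* (-1.17 ± 0.23, adjusted p = 0.00391) and miR-940 (-1.02 ± 0.23, adjusted p = 0.00875) also fell. By list, 2 of 12 miRNAs reported as silenced and 2 of 3 neuron markers rose (in both, miR-9 and miR-9*), 2 of 13 of the cisplatin response list rose (miR-21 and miR-21*), and 1 of 3 of the miR-371 to miR-373 list, 1 of 14 of the 14q32 list and 1 of 3 of the blood and endothelium list fell. All of these counts were the same adjusted over the list alone. The miR-17-92 list had a median of -0.29, -0.27 within slide 3, -0.57 with total signals and 0.15 with the series matrix (camera adjusted p = 0.0383, and 0.713 with an estimated correlation). Within slide 3 all 12 kept their direction, 9 at least 2-fold, and 11 were called with the slide as a block, miR-940 not among them. The split of 7 higher and 5 lower became 36 and 2 with the series matrix, 8 and 9 with total signals and 2 and 0 with normexp correction, which left miR-630 and miR-21. Calls ended without R replicate 2 for miR-9 (0.95), miR-21 (1.07), miR-150* (-0.997) and miR-940 (-0.66), without R replicate 1 for miR-21* (0.82), without RT replicate 1 for miR-21* (1.17) and miR-940 (-0.96) and without RT replicate 2 for miR-21 (0.92) and miR-21* (1.102), and the count was 22 without R replicate 1, 8 without R replicate 2 and 7 with only the arrays of the line.

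In OVCAR3, miRNAs of the C19MC cluster, a primate-specific imprinted cluster known for its expression in placenta, were higher in RT than in R. 25 of its 32 tested members rose (25 adjusted over the list alone), out of 28 miRNAs that rose in all. miR-512-3p rose at least 33.0-fold (adjusted p = 4.99e-17), miR-520c-3p at least 24.3-fold (adjusted p = 2.79e-14), miR-525-5p at least 10.7-fold (adjusted p = 2.62e-20) and miR-520a-5p at least 8.55-fold (adjusted p = 9.73e-22). miR-517b, already detected in R, rose by 3.91 ± 0.08 (adjusted p = 8.93e-15). Of the 45 miRNAs of this cluster on the array, 7 were detected on both arrays in S, 7 in R and 32 in RT. The 32 tested members are those detected in RT, and most of them passed the detection filter through that group alone. The share called, the list median and the camera result are therefore partly fixed by the filter, while the detection counts out of 45 are not. The list median was 2.26, and 2.34 and 2.20 within slides 1 and 2 (camera adjusted p = 4.01e-35, 0.00704 with an estimated correlation and 7.55e-33 with the slide as a block). It was 1.46 with quantile normalisation, 3.80 with total signals and 4.34 with the series matrix. The other 3 were miR-203 (1.83 ± 0.05, adjusted p = 2.95e-13), miR-21* (1.85 ± 0.30, adjusted p = 2.42e-04) and miR-923_v12.0 (1.72 ± 0.50, adjusted p = 0.0177), named after their values were seen except miR-21*. Of the list reported as silenced 3 of 12 rose (miR-512-3p, miR-512-5p and miR-203), and of the cisplatin response list 1 of 13 (miR-21*), the same counts as adjusted over the list alone. No miRNA fell at least 2-fold by limma (0 called), 12 of the 65 past the adjusted threshold alone were lower, and 78 had an unadjusted p under 0.05. The miR-200 family, repressors of ZEB1 and ZEB2 in epithelial cells, was lower as a list by camera (adjusted p = 0.00170, and 0.0490 with an estimated correlation), with 5 of 6 members lower, such as miR-141 at -0.86 and miR-200c at -0.73, and 0 called over all miRNAs or adjusted over the list alone. Its median was -0.35, and -0.38 and -0.31 within slides 1 and 2 (0.00210 with the slide as a block). With quantile normalisation it was -0.77 and with the series matrix -1.13, each with 2 members called lower. All 28 kept their direction within slides 1 and 2, with 28 and 27 at least 2-fold, and 28 were called with the slide as a block. The split of 28 higher and 0 lower became 22 and 11 with quantile normalisation, which ended the call of miR-21*, as did normexp correction, 36 and 13 with the series matrix and 45 and 0 with total signals.

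**Figure D2:**
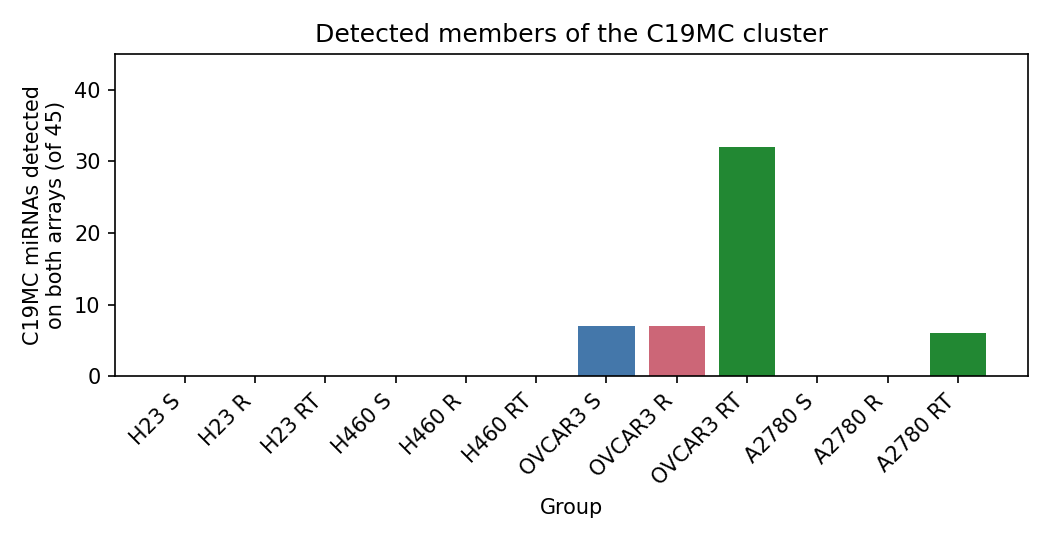
Number of C19MC miRNAs, out of 45 on the array, with a probe well above background on both arrays of each of the 12 groups (bars, axis from 0). The count was 7 in OVCAR3 S and R, 32 in OVCAR3 RT, 6 in A2780 RT and 0 in the remaining groups.

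In A2780, 12 miRNAs rose and 3 fell with the drugs. After miR-7 and miR-132, miR-21* rose by 1.66 ± 0.30 (adjusted p = 0.00130), miR-630 by 1.61 ± 0.15 (adjusted p = 2.16e-06) and miR-1225-5p by 1.53 ± 0.21 (adjusted p = 1.21e-04). miR-199b-5p changed by -1.29 ± 0.09 (adjusted p = 5.14e-08), miR-374a by -1.05 ± 0.27 (adjusted p = 0.0144) and let-7e by -1.05 ± 0.33 (adjusted p = 0.0451). let-7e was the 1 called member of 9 in its family, and 0 passed adjusted over the list alone. The stroma list holds miR-143, miR-145, miR-199 and miR-214 forms, typical of mesenchymal cells. Its 5 tested members were all miR-199 and miR-214 forms, since no miR-143 or miR-145 form was detected in any group. All 5 were below R and 1 was called (1 adjusted over the list alone). Values were -0.65 for miR-214*, -0.64 for miR-199a-5p, -0.62 for miR-214 and -0.60 for miR-199a-3p. Its median was -0.64, and -0.76 within slide 3 (camera adjusted p = 2.58e-09, 0.00410 with an estimated correlation and 1.13e-08 with the slide as a block), and 2 members were called with quantile normalisation and 0 with normexp correction by limma. 3 of 13 miRNAs of the cisplatin response list rose (3 adjusted over the list alone), miR-21, miR-21* and miR-185. Within slide 3 all 15 kept their direction and were at least 2-fold, and 14 were called with the slide as a block, miR-185 not among them. The split of 12 higher and 3 lower became 11 and 5 with quantile normalisation, 84 and 1 with the series matrix, 33 and 1 with total signals and 5 and 0 with normexp correction, which ended the calls of miR-630, miR-1225-5p, miR-199b-5p, miR-374a and let-7e. With only the arrays of the line 2 miRNAs were called. Without RT replicate 1, 9 miRNAs were called, with miR-21 (0.84), miR-21* (0.99), miR-185 (0.82), miR-374a (-1.004) and let-7e (-0.55) not among them, without R replicate 1 miR-185 (0.90), miR-374a (-0.98) and let-7e (-1.02) were lost, and without R replicate 2 let-7e (-1.07).

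The design asks which miRNAs lost in resistance are regained with the drugs. In H23, 4 of the 23 fallen miRNAs rose in RT (17.4%), namely miR-7, miR-132, miR-363 and miR-9*, and in A2780 4 of 11 (36.4%), namely miR-7, miR-630, miR-1225-5p and miR-575 (-1.11 and 1.08). miR-7 was the 1 miRNA in both sets. The fall and the rise in H23 use the same dim R arrays, where miR-7, miR-363 and miR-9* were not well above background. For miR-363 and miR-9* the bound on the rise, given above, was under 2-fold. Relative to parental cells, RT cells had -2.08 for miR-7 and 1.22 for miR-132 in H23, and 1.91 for miR-7 in A2780. In H460 and OVCAR3 the count was 0, with 0 and 2 fallen miRNAs to begin with (limma, 50 and 62 at an unadjusted p under 0.05 in R against S). The H460 count was 4 without R replicate 1 and 3 without a minimum fold. In A2780, let-7e was the 1 miRNA that rose in R and fell in RT. Independent lists would share 1.84 miRNAs in H23, 0.557 in A2780 and 0.236 in OVCAR3. In 100 simulations of unchanged groups sharing the R arrays no miRNA was called both ways (0 in every line). With nothing changed hardly any miRNA can be called in either contrast, so this count could hardly differ from 0. It does not show how often shared R arrays would add such calls among changed miRNAs. The covariance of both changes across miRNAs was -0.0182 in H23, -0.0676 in H460, -0.0243 in OVCAR3 and -0.138 in A2780, against simulated values of -0.0135, -0.0138, -0.0133 and -0.0132. With 1 R array for R against S and the other for RT against R, the covariances of both assignments averaged -0.00824, -0.0304, -0.0203 and -0.127, and in H23 they were 0.0134 and -0.0299. Between the R arrays of every line the slide differs as well. They lay on slides 1 and 2 in H23 and OVCAR3 and on slides 3 and 2 in H460 and A2780. In H460 and A2780, R replicate 2 shared no slide with the S or RT arrays of its line. The 4 miRNAs named above for each of H23 and A2780 were then called both ways in either assignment, along with miR-31 in 1 assignment of H23, and 0 in H460 and OVCAR3 (limma). The H23 count was 0 with quantile normalisation and with normexp correction, 15 with total signals, 10 with the series matrix, 8 with the brightest probe and 3 and 7 without RT replicate 1 and RT replicate 2. The A2780 count was 2 with quantile normalisation, 9 with total signals, 7 with the series matrix and 1 with only the arrays of the line. Without a minimum fold the counts in H23 and A2780 were 21 and 10. miR-575 was not called for R against S without S replicate 2 (-0.98) or for RT against R without RT replicate 1 (0.87).

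Across the 4 lines, with the line as the replicate, no miRNA passed in any contrast. limma called 0 for R against S, RT against R and RT against S, with 4, 15 and 21 at an unadjusted p under 0.05, and without H23 2 for RT against R and 2 for RT against S. The series matrix and normexp correction each gave 1 for RT against R and 1 for RT against S, and quantile normalisation 1 for RT against S, as did leaving out replicate 2. miR-7 was lower in R in 3 of 4 lines (-1.60 ± 0.88, 95% interval -3.68 to 0.48, adjusted p = 1) and higher in RT than in R in 4 of 4 (1.95 ± 0.88, interval -0.14 to 4.03, adjusted p = 0.628). The smallest p of RT against S was that of miR-183, at 0.71 (adjusted p = 0.141), and of RT against R that of miR-923_v12.0, at 1.33 (adjusted p = 0.381). miR-183 and miR-192 had 0.54 and 0.69 for RT against R, and miR-22 had 0.86 for RT against S. miR-10b (-0.68), miR-342-3p (-0.34) and miR-18b (-0.25) had the smallest p among miRNAs lower in R, and miR-885-5p (0.63), miR-768-3p_v11.0 (0.39) and miR-331-3p (0.34) among those higher. For RT against R the lower ones were miR-885-5p (-0.48), miR-20a (-0.33) and miR-361-5p (-0.29), and for RT against S miR-18a (-0.78), miR-17 (-0.44) and miR-18b (-0.36). The sign was the same in 4 lines for 3, 34 and 24 of 237 miRNAs, where chance gives 12.5% of miRNAs without floor values.

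By camera across lines, the miR-17-92 list was lower in R than in S (median -0.27, adjusted p = 8.91e-05), in RT than in R (-0.13, 0.00189) and in RT than in S (-0.40, 1.50e-07), with adjusted p of 0.463, 0.474 and 0.463 with an estimated correlation. H23 carried the first of these, with a list median of -0.91 against -0.03 in H460, 0.02 in OVCAR3 and -0.18 in A2780. For RT against R the medians were 0.05, -0.29, -0.05 and -0.28 in the same order. Of the 14 members, 2, 3 and 7 were lower in all 4 lines in the 3 contrasts. The study candidates, chosen on these samples, were lower in R (median -0.44, adjusted p = 0.0387, and 0.463 with an estimated correlation). The neuron markers were lower in R (-0.32, 0.0387) and higher in RT than in R (0.71, 0.0387), and the miRNAs reported as silenced were higher in RT than in R (0.45, 0.0484), each with an adjusted p of 0.463 with an estimated correlation. The C19MC list was higher in RT than in R (0.56, 0.0387) and than in S (0.56, 0.0286), both 0.972 with an estimated correlation. OVCAR3 carried the first of these, with a mean change over members of 2.05 against 0 in H23, -0.03 in H460 and 0.05 in A2780. The miR-200 family was lower in RT than in R (-0.07, 0.0371, and 0.535 with an estimated correlation), and the stroma list lower in RT than in R (-0.16, 0.00200) and than in S (-0.25, 0.00771), with 0.474 and 0.535. The stroma values come from A2780 alone, since in H23, H460 and OVCAR3 all members were at the floor, and 0 members of the miR-200 family were lower in all 4 lines. Without H460 R replicate 2 the neuron calls (0.0741 and 0.0741), the call of the silenced list (0.0741) and the C19MC call for RT against R (0.0583) were lost, and with the slide as a block the neuron call for RT against R (0.0812) and that of the silenced list (0.0730). Without that array the let-7 family was called higher in R than in S (0.0470, against 0.310 with all arrays and 0.972 with all arrays and an estimated correlation). The remaining lists had no camera call in any contrast: their smallest adjusted p were 0.0654 for p53-induced miRNAs, 0.553 for the cisplatin response, 0.763 for blood and endothelium and 0.370 for the miR-371 to miR-373 and miR-302 with miR-367 clusters. No member of the Xq27 or muscle lists was tested (0 and 0), and liver had 1, too few for camera.

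The changes differed between lines beyond the spread between duplicate arrays. The moderated F test of limma called 124 of 237 miRNAs for unequal changes in R against S and 123 in RT against R. The duplicates are not known to be separate cultures, so a difference between lines cannot be told apart from variation between cultures. miR-221 rose in H23 (1.59) and fell in A2780 (-1.06, F test adjusted p = 2.70e-07), and miR-29b rose in OVCAR3 (1.499) and fell in H23 (-2.18, adjusted p = 4.52e-04). With the drugs, miR-630 (adjusted p = 9.81e-08), miR-132 (adjusted p = 1.04e-09) and miR-512-3p (adjusted p = 6.36e-15) differed between lines, as did miR-150*, which rose in H23 (at least 1.58-fold) and fell in H460 (-1.17, adjusted p = 2.19e-04). Lung and ovarian lines did not part by limma (0 called in either contrast, 12 and 15 at an unadjusted p under 0.05, smallest adjusted p = 0.760 and 0.656). With the series matrix 23 miRNAs were called for RT against R in that comparison, and without replicate 1 of each group 2 for R against S. With the slide as a block the F test called 127 and 122 miRNAs, with normexp correction 208 and 30, and with the series matrix 76 for RT against R.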

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

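All tests of technical explanations in this part were chosen after the results they bear on were seen. The fit with the slide as a block was chosen beforehand as another way to process the data, but its use here was chosen afterwards, in place of a bound of 1 on within-slide changes that the H23 rise of miR-7 and 1 of the 6 changes in A2780 had missed.

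miR-7 fell in R and rose in RT in H23 and A2780. For the falls, a slide or scan difference is argued against by the smallest within-slide fall, which was 3.06 on the log2 scale, and array-wide signal by the smallest unscaled fall, 2.57 in A2780, where miRNAs detected on all arrays had a median unscaled change of 0.56 (SD 0.80). In H23, where values are fitted against R not well above background, the unscaled change was -3.47 against a median of -0.80 (SD 0.78). For the A2780 rise the same tests gave 5.02 and 5.05. In H23 each group had 1 array on slide 1 and 1 on slide 2, so a constant slide difference cancels by design. The H23 rise was at least 2.28-fold within either slide (fitted as 0.952 or more). It was called by limma with the slide as a block (adjusted p = 1.29e-04), which cannot alter the fitted change, so these values add little further evidence. Array-wide signal stays open for the H23 rise, at an unscaled 0.755 against a median of 0.21 (SD 0.40). The falls in both lines and the A2780 rise may be biological, a hypothesis found and tested on the same arrays, whose duplicates are not known to be separate cultures.

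C19MC miRNAs rose in OVCAR3 RT. Most of the 32 tested members passed the detection filter through that group alone, so the size of their median rise is partly fixed by the filter. Each OVCAR3 group had 1 array on slide 1 and 1 on slide 2, so a constant slide or scan difference cancels by design. The within-slide median of 2.20 or more on the log2 scale adds little to that. RNA of another line of this series is argued against by the count of members detected in other lines, 6 at most (in A2780 RT) against 32 in OVCAR3 RT. Whether all 32 detected members carry RNA cannot be told apart from near-identical members read by one another's probes, because probe sequences were not used here. A response of the cluster to the drugs stays among the open explanations, as untested.

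miR-630, miR-575 and miR-1225-5p fell in R and rose in RT in A2780, and miR-575 and miR-1225-5p also rose in H23 RT and miR-630 in H460 RT. A slide difference is argued against, since all 6 changes in A2780 kept their direction within slide 3 (0.982 or more in size) and were called with the slide as a block, the smallest at 1.08 (adjusted p = 0.0189). Their differences between duplicate arrays had a mean correlation of 0.471, and 92.9% of 10000 random sets of 3 miRNAs had a lower one, so array-to-array variation that these miRNAs share may account for part of the pattern and cannot be told apart from a response of the cells.

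Among the miRNAs named across lines, 36 sets of 4 line changes were examined for a line far from the other 3, and 8 had one. Chance gives about 1 in 20 for independent sets without ties, which does not hold here, because several sets have lines tied at the floor and arms and contrasts of 1 miRNA are related. For R against S these were miR-148a in OVCAR3 (0.92), miR-335 in A2780 (-2.01), miR-335* in A2780 (-2.58) and miR-132* in H23 (-0.0276, fitted against R not well above background). For RT against R they were miR-7 in A2780 (4.93) and miR-335* in H460 (-0.39), and for RT against S miR-335 (-1.90) and miR-335* (fitted -2.61, with RT not well above background) in A2780. For miR-132* in R against S and miR-335* in RT against S the other 3 lines all had a change of 0, and miR-335* was detected on 0 arrays of H460 R and of H460 RT.

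The 4 lines differed in R against S for 124 miRNAs and in RT against R for 123 by the moderated F test. That test is set against the spread between duplicate arrays, so variation between cultures cannot be told apart from a difference between lines. Opposite calls in 2 lines were seen for miR-221 with resistance (1.59 in H23, -1.06 in A2780), miR-29b with resistance (1.499 in OVCAR3, -2.18 in H23) and miR-150* with the drugs (at least 1.58-fold in H23, fitted as 1.13, and -1.17 in H460), with F test adjusted p of 2.70e-07, 4.52e-04 and 2.19e-04.

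Viral miRNA probes, which entered no comparison, gave signals well above background. kshv-miR-K12-3 was detected on both arrays of 12 groups, ebv-miR-BART13 of 9 and hsv1-miR-LAT_v10.1 of 6, out of 76 viral names.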

How the results depend on the processing

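Of these tests, those with normexp correction, a minimum spread, the weakest array left out of the comparisons across or between lines and of the lists, and the slide as a block for the lists were chosen after the data were seen. No single named miRNA reversed past the threshold under any alternative run. The balance of higher and lower calls turned from 9 and 11 to 26 and 11 (series matrix) and 11 and 10 (quantile) in A2780 R, and from 7 and 5 to 8 and 9 (total signals) in H460 RT, and list medians changed sign with normexp correction for let-7 in A2780 R (0.40 to -0.27) and HOX in H460 R (-0.31 to 0.16), and with the series matrix for miR-17-92 in H460 RT (-0.29 to 0.15). For these lists, the median over all 237 miRNAs in the same contrast and setting was -0.85, 0.32 and 0.47. Against it let-7 was still higher and HOX and miR-17-92 still lower. Over the 48 miRNAs detected on all arrays it was -0.30, 0.07 and 0.46, which leaves HOX higher. The sign changes are therefore in part shifts of most miRNAs with the scaling. Over 463 named values and their alternatives, 6616 comparisons kept their side of the threshold, 158 dropped below it and 224 rose above it. Signal over background limits the dim miRNAs, since 42.9% of the tested values lay at the floor, where a change has no size. Where no cause is stated below, the cause was not tested.

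With quantile normalisation the calls were 3 for R against S in H460, 7 for RT against R in H23, 0 and 2 for miRNAs lower in R and higher in RT in H23 and A2780, and 1 across lines for RT against S. With total signals they were 55 in H23 and 31 in OVCAR3 for R against S, 55 in H23, 45 in OVCAR3 and 34 in A2780 for RT against R, and 15 and 9 lower in R and higher in RT in H23 and A2780. With the brightest probe they were 42 in H23 and 1 in H460 for R against S, 30 in H23 for RT against R and 8 for both changes in H23. With the series matrix they were 73 in H23, 19 in OVCAR3 and 37 in A2780 for R against S, 34 in H23, 38 in H460, 49 in OVCAR3 and 85 in A2780 for RT against R, and 10 and 7 for both changes in H23 and A2780. The lines then differed in RT against R for 76 miRNAs, 1 was called across lines for RT against R and 1 for RT against S, and 23 between lung and ovarian lines for RT against R. Its normalisation is not known.

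Restricting the tests to the 48 miRNAs detected on all arrays, which leaves fewer to call, gave 8 in H23, 3 in OVCAR3 and 8 in A2780 for R against S, 2 in H23, 2 in H460, 1 in OVCAR3 and 7 in A2780 for RT against R, 0 and 1 for both changes in H23 and A2780, 40 and 7 for lines that differ, and 1 and 2 across lines for RT against R and RT against S. Normexp correction, whose offset of 50 compresses dim signals, gave 6 in H23 and 6 in OVCAR3 for R against S, 2 in H23, 2 in H460 and 5 in A2780 for RT against R, 0 for both changes in H23, 208 and 30 for lines that differ, and 1 and 1 across lines for RT against R and RT against S. Without a minimum fold, R against S gave 75 in H23, 12 in H460, 40 in OVCAR3 and 49 in A2780, RT against R gave 72, 36, 65 and 37 in the same order, and both changes gave 21 in H23, 3 in H460 and 10 in A2780. With only the arrays of the line, which leaves fewer arrays to estimate the spread, R against S gave 12 in A2780, RT against R gave 12 in H23, 7 in H460 and 2 in A2780, and both changes gave 1 in A2780. Of the 24 camera calls, 4 held with an estimated correlation.

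Leaving out arrays or lines, where the lone array is assumed to vary like those of other groups, gave 0 to 13 (without R replicate 1, and 1 without S replicate 1) for R against S and 8 (without R replicate 2) to 22 (without R replicate 1) for RT against R in H460, and 9 (without RT replicate 1) to 17 (without RT replicate 2) for RT against R in A2780. For both changes it gave 3 (without RT replicate 1) to 7 (without RT replicate 2) in H23 and 0 to 4 (without R replicate 1) in H460. Across lines it gave 0 to 2 (without H23) for RT against R and for RT against S (1 without replicate 2), and between lung and ovarian lines 0 to 2 (without replicate 1) for R against S. F tests without replicate 1 or replicate 2 had no residual degrees of freedom and were not run.

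Median changes moved with the scaling. Over the 237 miRNAs they ran from -0.44 to 0.47 with the series matrix, from -0.85 to 0.55 with normexp correction and up to 0.22 with total signals, against at most 0.12 as reported. Over the 48 miRNAs detected on all arrays, quantile normalisation shifted the median by -0.23 to 0.11, total signals by -0.25 to 0.33, the series matrix by -0.66 to 0.72 and normexp by up to 0.13.

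The replicate numbers were not taken to pair the arrays, since 6 of 12 correlations of deviations between groups of a line were above 0.1, with a range from -0.62 to 0.48. In OVCAR3 all 3 were (0.371, 0.449 and 0.430), where the number is also the slide, as in H23. With the replicate number as a block, 27, 0, 11 and 20 miRNAs were called for R against S in H23, H460, OVCAR3 and A2780, and 19, 11, 28 and 14 for RT against R. The F tests called 120 and 124, and 2 named calls ended, miR-21* in H460 RT and let-7e in A2780 RT. With the slide as a block, 23 camera calls were made, and without the weakest array 22, counts that include calls gained (neuron markers in H23 R with both, let-7 across lines for R against S with the second). With no detection filter, a minimum spread or the slide or replicate number as a block, all counts of calls stayed within 1.5 times. The 75th percentile over all human probes was not run as a reference, since it was not above 0 on 6 of 24 arrays (range -4.35 to 8.79). Normexp on mean signals was not run because the files used here hold median signals.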

Other observations

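No tests in this part were chosen after the result was seen, and the detection counts were not tested.

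The lines differed in which miRNA families were detected at all. Members of the miR-200 family, typical of epithelial cells, were detected on both arrays in OVCAR3 (5 of 9 in S, 6 in R and 5 in RT), 2 in H460 RT and 0 in the other groups. The stroma list (miR-143, miR-145, miR-199 and miR-214 forms) had 5 of 9 detected in each A2780 group and 0 in the other lines. The 5 were the miR-199 and miR-214 forms, and miR-143 and miR-145 were detected in no group. let-7 members on the array numbered 16, of which 9 were detected in every group of H23 and OVCAR3, 9, 7 and 9 in H460 S, R and RT, and 3, 6 and 6 in A2780.

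Of 26 miRNAs reported as silenced by promoter methylation, detection on both arrays went from 9 in S to 1 in R and 7 in RT in H23, and from 6 to 2 and 6 in H460. The H460 R counts on both arrays are limited by the weak R replicate 2, with 86 human miRNAs detected against 138 on R replicate 1 and 133 and 141 in S. In OVCAR3 the counts were 3, 6 and 8 and in A2780 4, 4 and 8. The neuron markers, of which miR-9 and miR-124 are also in that list, went 3, 1 and 3 in H23 and 3, 0 and 3 in H460. In OVCAR3 they went 1, 2 and 2 and in A2780 1, 1 and 3. All human miRNAs together went 145, 87 and 132 in H23 and 132, 83 and 117 in H460. The 6 C19MC members detected in A2780 RT were miR-512-3p, miR-517a, miR-517b, miR-517c, miR-520c-3p and miR-520f, and the 7 in OVCAR3 S and R were miR-516a-5p, miR-517a, miR-517b, miR-517c, miR-518e*, miR-521 and miR-522, named after their values were seen.

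For the comparisons across lines, limma called 0 miRNAs for R against S, 0 for RT against R and 0 for RT against S, with 4, 15 and 21 at an unadjusted p under 0.05. The highest counts over the other splits that part the samples of every line were 1, 0 and 1. The 8 splits of each comparison are too few for a share under 0.05.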
